A study of Homo sapiens with 3 samples.

How the data were processed

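Total RNA from the human lung adenocarcinoma line NCI-H1650 was measured on 3 Affymetrix HG-U133 Plus 2.0 arrays carrying 54675 probe sets. One array held control cells, one held cells exposed to 40 μM of the fungal triterpenoid colossolactone H for 12 h, and one held cells exposed to that dose for 24 h. Per the labels, the treated cultures were started from 1000000 cells in a 10 cm dish, and for all arrays RNA was extracted with Trizol, and biotinylated cRNA was made from 6 μg of RNA. The labels state neither the time at which the control was collected nor a vehicle. Each group held 1 array, so 3 arrays in 3 groups gave no replicate spread.

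The deposited values were linear signal intensity made with MAS5, per the submitters' processing notes, and its version and settings were not given in the sources used here. The mean signal after trimming 2% from each end was 500 on every array, which is how a common MAS5 target shows in the values. Median signals were 61.7 in the control, 60.6 at 12 h and 61.8 at 24 h. No further scaling was applied.

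Probe sets were named from the platform annotation supplied with the values. It gave 1 gene for 41097 probe sets, several genes for 1801 and none for 11777. Of the probe sets with 1 gene, 41043 matched a current gene record through the Entrez identifier, and 6 symbols were updated. Probe sets of several genes were never reported as genes. A gene took the value of its brightest single-gene probe set over the 3 arrays, which gave 19775 genes. Signals below the 50th percentile of all values, 61.4, were set to that floor, and a gene counted as measured when it exceeded the floor on at least 1 array, as 12341 genes did. Where a gene lay at the floor on one of the arrays compared, its difference is a bound. Array control probe sets were read as checks of RNA and hybridisation quality only.

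The 3 comparisons were 12 h against control, 24 h against control and 24 h against 12 h. Each value was the log2 difference of a pair of arrays, and genes were counted at 2-fold or more. No p-value or standard error can be given without replicates. The gene lists, the size threshold, the naming rule and the 10 processing alternatives were fixed before the data were examined. The 39 gene lists hold 841 different genes, of which 758 were on the arrays and 693 were measured. For each list the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list was called higher or lower when it lay outside the central 95% of random lists, and lists with fewer than 5 measured genes were not placed. This percentile treats genes as independent, which genes of one pathway are not, and it describes these arrays only.

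Genes are named by a fixed rule. For each comparison with the control it took up to 8 genes each way with the largest differences, above the floor on both arrays and backed by at least 2 single-gene probe sets, all moving the same way and at least 2 of them by 2-fold. It also took up to 4 genes each way that lay at the floor on one array, up to 4 each way for 24 h against 12 h, and up to 4 members of each list with the largest mean difference from the control. CDKN1A, MDM2, GADD45A, DDIT3, ATF3, HMOX1, EGFR, CCND1, CCNB1 and MKI67 were named whatever their value, and 1 further gene of that group and 1 gene list are not reported here. Members of a list are also named where the text counts 5 or fewer of them. The remaining named genes were chosen after their values were seen, and the text says so where it names them.

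Because both treated arrays were compared with the same control array, 100 simulated pairs of unchanged arrays sharing that control were drawn. Their noise was taken from the difference between the treated arrays at each signal level, which holds real change as well. The control was given the same noise as the treated arrays, which could not be tested with 1 control array. The procedure was also tested on simulated data built on the mean of the 3 arrays, over 12591 genes with 200 planted changes. Noise came from the difference between the treated arrays, and results were read for 24 h against control. Over measured genes the robust SD was 0.183 for 24 h against 12 h and 0.294 for 24 h against control. The simulated noise may thus be smaller than that of a comparison with the control. Of planted 1.5-fold changes that were measured, 1 of 50 was called. For 3-fold changes 91 of 98 were called, and for 4-fold changes 43 of 48. Among 12371 unchanged genes 54 were called. A list of 24 genes shifted by 0.3 had a median of 0.26 at percentile 100, set against 2000 random lists. Of 40 unshifted lists of randomly drawn genes with independent noise, 2 lay outside the central 95%.

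Alternatives covered the scaling between arrays (median centring, quantile normalization and cyclic loess), the floor (the 25th percentile, the 65th percentile, or no floor with a pseudocount of 1), the probe set of a gene (the median over its probe sets, or only probe sets with the plain identifier suffix that marks probes specific to one transcript), and the threshold (3-fold, or 3 times the local robust SD). Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures were drawn with matplotlib 3.10.9, and cyclic loess was run in R 4.3.3 with limma 3.58.1. No value column was left out. No genome coordinates are given, since the sources used here name no build.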

Results

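The series asked how the transcriptome of NCI-H1650, an established human lung adenocarcinoma line, differed after exposure to colossolactone H, a triterpenoid from the fungus Ganoderma colossum. One array each was made from control cells, from cells exposed to 40 μM for 12 h and from cells exposed for 24 h. Signal above the floor of 61.4 was found for 27375 of 54675 probe sets in the control, 27242 at 12 h and 27397 at 24 h. There were no replicates, so every difference describes these 3 arrays, carries no error or p-value, and is limited in precision by their number. Differences are log2 of treated over control signal unless a fold is given.

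At 12 h the integrated stress response stood out, with DDIT3 (Entrez gene 1649), the stress-induced transcription factor CHOP, 3.19-fold higher and HMOX1 (Entrez gene 3162), the haem-degrading oxidative stress enzyme, also 3.19-fold higher than in the control. Sterol synthesis genes were higher, among them HMGCS1 (Entrez gene 3157), the cytosolic HMG-CoA synthase, by 1.93-fold. ABCA1 (Entrez gene 19), the cholesterol efflux transporter, was 5.18-fold lower, and genes of DNA replication were lower as a group. In all, 54 genes were 2-fold or more higher and 53 were 2-fold or more lower, together 0.867% of 12341 measured genes. Of these 107 genes, 23 lay at the floor on one of the arrays. Only 27 had 2 or more single-gene probe sets above the floor on both arrays. All probe sets moved the same way for 23 of those 27, and a second one reached 2-fold for 11. Of the 38 gene lists that could be placed, 9 lay above and 5 below the central 95% of matched random lists. If genes varied independently 1.9 would lie outside, but genes of one pathway do not, so more may do so without an effect of the compound.

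The ATF4 and integrated stress response list had the highest 12 h median of the 38 lists, 0.68 against a random range of -0.06 to 0.09. Of its 30 members 29 were higher, and VLDLR at -0.27 was the exception. The 6 members that were 2-fold higher were DDIT3 (649.5 to 2071 signal units), CHAC1 at 1.37, a glutathione-degrading enzyme, NUPR1 at 1.36, a stress-induced chromatin protein, TRIB3 at 1.19, a pseudokinase induced by CHOP, ASNS at 1.09, the asparagine synthetase, and PSPH at 1.09, the last enzyme of serine synthesis. ATF4 itself, named after its value was seen, was at 0.68, and ATF3 was at 0.09, or -0.11 as the median over its probe sets. TRIB3 and PSPH were named after their values were seen. The 1 bright probe set of ASNS matches several transcripts, and a transcript-specific probe set near the floor gave at least 0.19. For PSPH the probe sets of the gene ranged from -0.23 to 1.60.

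Endoplasmic reticulum chaperones and genes of the unfolded protein response had a median of 0.20, with 20 of 23 members higher. HSPA5, the chaperone BiP, stood at 13606 signal units in the control and 21919 at 12 h, a difference of 0.69. ERN1, the stress sensor IRE1, was at 0.80 and DERL3, a factor of protein disposal from the reticulum, at 0.69 from a signal of 66.1 near the floor, a direction that turned to -0.20 with transcript-specific probe sets. The 3 lower members were CREB3L2 at -0.66 (-0.10 with transcript-specific probe sets), EDEM1 at -0.11 and SEL1L at -0.00.

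NRF2 targets, the genes of the oxidative stress response, had a median of 0.22, and 22 of 25 were higher. HMOX1 went from 1146 to 3656 signal units. PGD, a pentose phosphate enzyme that makes NADPH, was at 1.06, AKR1C3, an aldo-keto reductase, at 1.06 and ME1, the NADPH-forming malic enzyme, at 0.85. AKR1C family members are close in sequence, so signal shared between them cannot be excluded for AKR1C3. NQO1 and TXNRD1, both named after their values were seen, were already bright in the control at 19116 and 16288 signal units and differed by 0.08 and 0.09.

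Cholesterol synthesis and uptake genes had a median of 0.52, and 17 of 19 were higher. MVD, mevalonate decarboxylase, was the 1 member that was 2-fold higher, at 1.04, followed by HMGCS1 at 0.95, EBP, a sterol isomerase, at 0.79 and SC5D, a sterol desaturase, at 0.64. INSIG1, the sterol-regulated retention protein of the reticulum, was at 0.55, a gene named after its value was seen. The 2 lower members were SREBF2 at -0.18, or 0.01 as the median over its probe sets, and TM7SF2 at -0.09. Lipogenic genes had a median of 0.22 with 11 of 13 higher, led by LPIN1, a phosphatidate phosphatase, at 1.07 and ACSS2, an acetyl-CoA synthetase, at 0.91. With the median over its probe sets LPIN1 was at 0.94. ME1 belongs to this list and to the NRF2 list.

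Among liver X receptor targets, genes that export and transport cholesterol, ABCA1 stood at 819 signal units in the control and 158 at 12 h, with both of its probe sets lower, and MYLIP, a ligase that degrades the LDL receptor, was at -0.63. NR1H3, a liver X receptor, was at 0.90 and SMPDL3A at 0.55, so the list went both ways, and its median of -0.28 lay within the random range, though below it under 2 of the 8 alternatives.

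DNA replication and G1/S genes had a median of -0.33, and 43 of 44 were lower, with RFC2 at 0.09 the exception. UHRF1, which maintains DNA methylation at replication forks, was at -1.04, CCNE2, a cyclin of S-phase entry, at -0.99, E2F8, a repressor of the cell cycle, at -0.91 and MCM2, a replicative helicase subunit, at -0.75. Homologous recombination and Fanconi repair genes had a median of -0.30 with 23 of 25 lower, including DNA2, a nuclease-helicase, at -0.75 and EXO1, a resection nuclease, at -0.52. G2/M and mitosis genes had a smaller median of -0.14, and 39 of 51 were lower. KIF15 and KIF11, both spindle motors, were at -0.50 and -0.46, while CCNB1, the mitotic cyclin B1, was at -0.01. MKI67, the proliferation antigen Ki-67, was at -0.42 and CCND1, cyclin D1, at -0.23.

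Smaller shifts were found in other lists at 12 h. Autophagy and lysosome genes had a median of 0.17 with 24 of 30 higher, among them ULK1, a starter kinase of autophagy, at 0.59 and GABARAPL1, an autophagosome protein, at 0.46. Interferon response genes had a median of 0.19 with 19 of 22 higher, among them RSAD2 at 0.68 and IRF9 at 0.44, and the 3 lower members were IFITM1 at -0.54, IRF1 at -0.30 and OAS3 at -0.27. Proteasome subunits were higher in 26 of 26 cases with a median of 0.12, led by PSMD3 at 0.73. Replication-dependent histone genes had a median of 0.30 with 8 of 8 higher, led by H2AC6 at 0.54, though the copies are near-identical and their probe sets may share signal. Probe sets that H2BC4 or H4C8 share with other histone genes entered no gene value and went both ways. They lay between -0.56 and 0.37, with the brightest at 0.04. Immediate early genes had a median of -0.19, with CCN2 at -0.91 and CCN1 at -0.86, both matricellular proteins, and NR4A1 at least 2.31-fold lower because it lay at the floor. Splicing factors had a median of -0.12, with U2AF2 at -0.32 and U2AF1 at 0.47. The calls for proteasome, histone, immediate early and splicing lists were not kept when only transcript-specific probe sets were used.

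Genes named for size and for agreement between probe sets were led by SLFN5, a Schlafen family member, which stood at 180.2 signal units in the control and 547 at 12 h, a difference of 1.60. PXK was at 1.25, KLHDC7B at 1.22, SLC1A4, an exchanger of alanine, serine and cysteine, at 1.13, HSPA6, a strictly inducible HSP70, at 1.11, RAB39B at 1.08 and NIBAN1 at 1.03. Lower genes were ABCA1 at -2.37, TGFB2, a transforming growth factor, at -1.35 and MOB3B at -1.09. Under alternative settings SLFN5 was at 0.56, SLC1A4 at 0.48 and MOB3B at -0.77 as medians over their probe sets, and HSPA6 was at 0.63 and RAB39B at 0.84 with the floor at the 65th percentile. Fewer genes met this rule than it allowed, and none met it with one array at the floor. A pair of genes outside the rule, chosen after their values were seen, were CBS, an enzyme of cysteine synthesis, at 1.56, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, at 1.28. CBS was at 0.19 when only transcript-specific probe sets were used.

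At 24 h the stress genes remained higher than in the control, with DDIT3 3.39-fold and GDF15, a stress-induced cytokine, 3.65-fold higher. Replication and mitosis genes were lower together, among them E2F8 by 3.08-fold and KIF11 by 2.10-fold. Proteasome subunits were higher, among them PSMD3 by 1.81-fold, and metallothioneins, small metal-binding proteins, were lower. The counts were 70 genes 2-fold or more higher and 77 lower, 1.19% of those measured, and 26 of these 147 lay at the floor on one array. Only 38 had 2 or more single-gene probe sets above the floor on both arrays. All probe sets moved the same way for 30 of those 38, and a second one reached 2-fold for 11. In the simulation with planted changes 54 of 12371 unchanged genes were called. Of 38 lists, 10 lay above and 7 below the random range.

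The ATF4 list had a median of 0.70 at 24 h, and again VLDLR, at -0.29, was the 1 member of 30 that was lower. DDIT3 was at 1.76, NUPR1 at 1.30, ASNS at 1.20, CHAC1 at 1.16, WARS1, the tryptophanyl-tRNA synthetase, at 1.12, PHGDH, the first enzyme of serine synthesis, at 1.09 and TRIB3 at 1.06, which made 7 members 2-fold higher. SLC7A11, the cystine importer held by both the ATF4 and the NRF2 list, was at 0.97 at 12 h and 0.84 at 24 h, and was named after its values were seen, like PHGDH. The ASNS probe set near the floor gave at least 0.06, and TRIB3 was at 0.96 as the median over its probe sets. Reticulum chaperones had a median of 0.24 with 19 of 23 higher. HSPA5 stood at 23108 signal units, a difference of 0.76, ERN1 was at 0.71, and XBP1 and HERPUD1, both named after their values were seen, were at 0.63 and 0.47. As the median over its probe sets XBP1 was at 0.16.

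NRF2 targets had a median of 0.44 at 24 h, with 23 of 25 higher and 4 of them 2-fold. PGD was at 1.34, HMOX1 at 1.27, ME1 at 1.18 and AKR1C3 at 1.01, and ME1 was at 0.78 as the median over its probe sets. TRIM16L was the 1 member that was 2-fold lower, at -1.28, and its median over probe sets was -0.64. Cholesterol genes had a median of 0.27 with 16 of 19 higher, HMGCS1 at 0.37, EBP at 0.49 and MVD at 0.34. The 3 lower members were SREBF2 at -0.47, STARD4 at -0.34 and INSIG1 at -0.28. Lipogenic genes had a median of 0.29 with 10 of 13 higher, including LPIN1 at 0.60 and FADS2, a fatty acid desaturase, at 0.46.

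Liver X receptor targets had a median of -0.35, just below the random range, with 5 of 7 members lower. ABCA1 was 3.08-fold lower, at 266 signal units, and NR1H3 was at 1.17. NR1H3 was at 0.86 with the floor at the 65th percentile. The list was not called with no floor, with transcript-specific probe sets or with the floor at the 25th percentile, where its median was -0.06.

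Replication and G1/S genes had a median of -0.50 at 24 h, and 43 of 44 were lower, with CCNE1 at 0.02 the exception. E2F8 was at -1.62, CCNE2 at -1.10, UHRF1 at -0.91 and MCM2 at -0.90. G2/M and mitosis genes had a median of -0.45, and 48 of 51 were lower. KIF11 was at -1.07, ESPL1, separase, at -0.94, MKI67 at -0.88 and KIF15 at -0.73, and TOP2A and CDK1, named after their values were seen, were at -0.79 and -0.49. The 3 members that were not lower at either time were CDC25B at 0.24, CKS1B at 0.23 and HMMR at 0.01, and CCNB1 was at -0.13. Homologous recombination and Fanconi genes had a median of -0.47 with 24 of 25 lower, among them DNA2 at -0.90, BLM, a helicase, at -0.76 and BRIP1 at -0.71. Excision, mismatch and end-joining genes, as a contrast, had medians of -0.05 and -0.01 at 12 h and 24 h, within the random range, with ERCC1 at 0.49 at 24 h and OGG1 at -0.85, the latter 0.00 as the median over its probe sets. On the array at 24 h the 3' over 5' signal ratio of ACTB, a sign of RNA integrity, was 6.55, against 4.95 in the control and 5.38 at 12 h, while that of GAPDH was 1.24, 1.21 and 1.25.

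The metallothionein list, which as set out also holds the transporter gene SLC30A1, had a median of -0.68 at 24 h with 7 of 7 measured members lower. Its median at 12 h was -0.07, within the random range. MT2A was at -0.74, MT1H at -0.70, MT1G at -0.69 and MT1X at -0.68. Their sequences are nearly identical, so these probe sets may report on one another. Proteasome subunits had a median of 0.32 and were higher in 26 of 26 cases, with PSMD3 at 0.85, PSMD4 at 0.68 and PSMC4 at 0.62. Autophagy and lysosome genes had a median of 0.16, with SQSTM1, a selective autophagy receptor, at 0.87 and CTSL, a lysosomal protease, at 0.67. Histones had a median of 0.37, interferon genes 0.15 and splicing factors -0.10, with H2AC6 at 0.65, OASL at 0.32 and U2AF2 at -0.49. The histone call was again not kept with transcript-specific probe sets. MAP kinase output genes had a median of 0.16 at 24 h, with ETV5 at 0.98 (0.31 with transcript-specific probe sets) and DUSP6 at 0.59 but SPRY1 at -0.51, and this call was not kept with cyclic loess, the floor at the 65th percentile or transcript-specific probe sets, the last giving a median of 0.04.

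Genes named for size and probe set agreement at 24 h were HSPA6 at 1.52, SLFN5 at 1.39, HSP90B1 at 1.37, NIBAN1 at 1.26, PXK at 1.12 and WARS1 at 1.12 on the higher side, although brighter probe sets that HSP90B1 shares in the annotation with another gene disagreed with one another. Lower genes were ABCA1 at -1.62, CCNE2 at -1.10 and MOB3B at -1.10, of which MOB3B was at -0.82 as the median over its probe sets. TGFB2 was at -1.78, and at -0.94 as the median over its probe sets.

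Markers of cells that a pure line should not hold were also read, although RNA of whole cultures cannot tell which cells gave a signal. Of 14 leukocyte markers 3 were measured, the brightest being CSF1R at 198.4, 186 and 179.5 signal units in the control, at 12 h and at 24 h, with ITGAM and HBB near or at the floor. Of 14 fibroblast and endothelial markers 5 were measured, of which COL3A1, COL1A1 and FAP had signals of 876.9, 729.8 and 470.9 in the control, above the 75th percentile of that array at 434.1. All 5 were lower at both times, with medians of -0.27 at 12 h and -0.56 at 24 h. COL3A1 was at -0.43 and -0.58, PECAM1 at -0.48 and -0.62, COL1A1 at -0.08, and -0.56, or 0.13 and -0.22 as medians over its probe sets, FAP at -0.14 and -0.41, and TEK at -0.27 and -0.30. The 24 h median lay below the random range with the floor as set, and within it with a lower floor or none.

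Several pathways often followed in drug-treated tumour cells lay within the random range in each comparison with the settings fixed beforehand. Pro-apoptotic BCL2 family and death receptor genes had medians of 0.08 at 12 h and 0.06 at 24 h, with PMAIP1, the BH3 protein NOXA, at 0.39 and 0.64 and TNFRSF10B, the death receptor DR5, at 0.40 and 0.50. Anti-apoptotic genes had medians of -0.02 and 0.06, with BCL2L1, the survival protein BCL-xL, at -0.53 and -0.45. ERBB receptors and ligands had medians of -0.14 and -0.19, with EGFR at -0.32 and -0.14 and MET at -0.44 at both times.

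Single genes named whatever their value included CDKN1A, the cell cycle inhibitor p21, at 0.19 and 0.06, MDM2, a ubiquitin ligase, at 0.18 and -0.01, and GADD45A, a growth arrest gene, at 0.39 and 0.45. GDF15 was at 1.58 and 1.87, and SESN2, a stress-induced sestrin of the ATF4 list, at 0.90 and 0.88. Heat shock genes had medians of 0.06 and 0.14, the latter called higher under 2 of the 8 alternatives, with HSPA6 the 1 member that was 2-fold higher, and hypoxia genes had 0.09 at both times, with STC2 at 0.88 and 0.94 and VEGFA at 0.57 and 0.64. Medians were 0.02 and 0.00 for NF-kB and cytokine genes, where IL1A was at 0.70 and 0.83, and 0.06 and -0.06 for FOXO targets, where CITED2 was at -0.44 and -0.70. Aryl hydrocarbon receptor targets had 0.08 and 0.05. CYP1A2, a xenobiotic oxidase of that list, was at -1.20 and -1.51 from 255.5 signal units, on a probe set that may hybridise to related transcripts, and at -0.41 at both times with the floor at the 65th percentile. Glucocorticoid receptor targets had -0.12 and 0.13, with TSC22D3 at 0.48 and 0.66. Glycolysis had 0.06 and 0.07, with HK2, a hexokinase, at 0.20 and 0.70. Oxidative phosphorylation had 0.07 and 0.01, with SDHC at 0.40 and 0.22 but at -0.08 and -0.34 on transcript-specific probe sets. Ribosomal proteins had 0.06 and 0.07, with RPS15 at 0.44 and 0.24. Drug efflux and phase II genes had 0.12 and 0.16, with ABCC3, a conjugate exporter, at 0.22 and 0.56 but at -0.29 and -0.43 on transcript-specific probe sets. Epithelial junction genes had -0.04 and -0.09, with CLDN4 at 0.69 and 0.79 and KRT19 at -0.54 and -0.60. Mesenchymal genes had -0.02 and 0.02, with TAGLN at 0.73 and 0.51, TWIST1 at 0.50 and 0.42 and THBS1 at -0.36 and -0.80, and CCN2 is counted in this list and among immediate early genes. Lung lineage genes had 0.00 and -0.13, with SFTPC at 0.93 and 0.64 and SFTPB at -0.36 and -0.34, both surfactant proteins, and housekeeping genes had 0.00 and 0.03, with ACTB at -0.19 and -0.17.

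**Figure D1:**
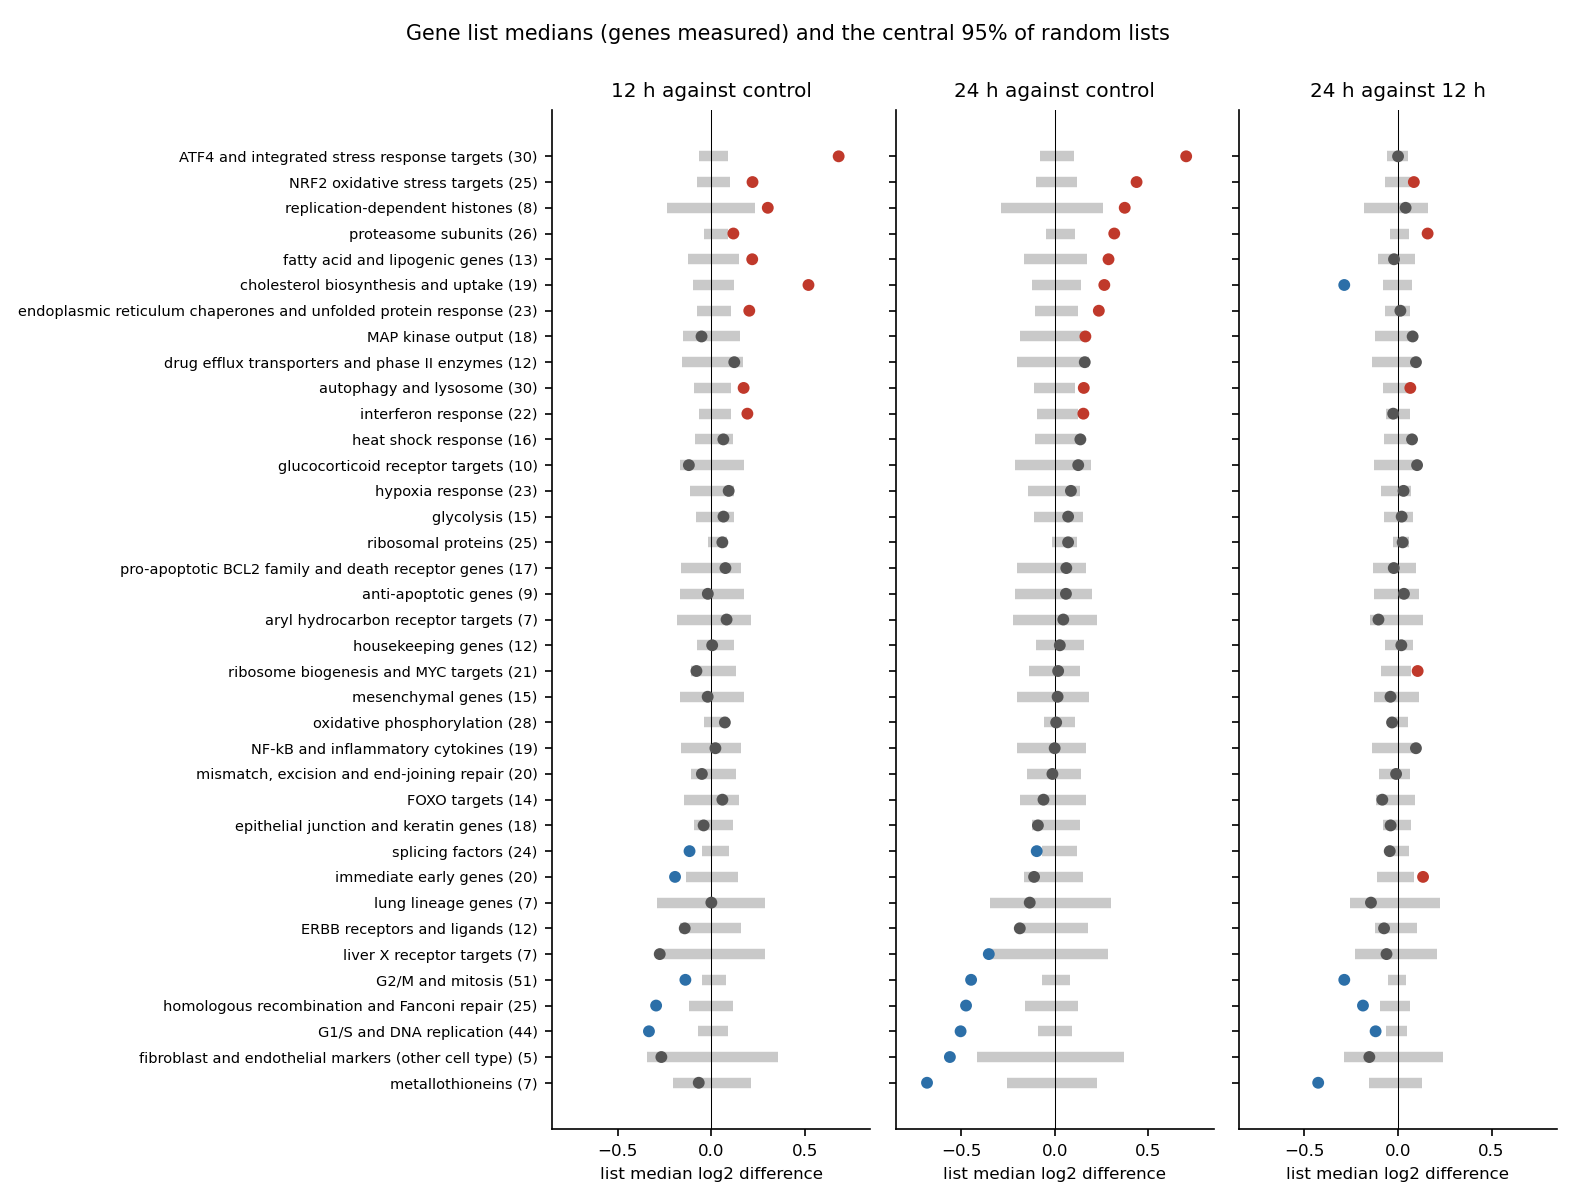
Each point is the median log2 difference of a gene list, with 1 panel per comparison, and grey bars span the central 95% of random lists of matched signal. Red points lie above the bar and blue points below it, with the ATF4 list at 0.68 and 0.70 against the control and metallothioneins at -0.68 at 24 h.

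Between 12 h and 24 h sterol synthesis genes were lower at the later time and mitotic genes were lower still, while proteasome subunits were higher. HSP90B1, the reticulum chaperone GRP94, stood at 3150 signal units at 12 h and 7303 at 24 h, a difference of 1.21, and at 2825 in the control. Its single-gene probe sets are of the kind that may hybridise to related sequences, and HSP90B1 values are uncertain for a further reason. A pair of probe sets annotated to HSP90B1 together with another gene, which entered no gene value, disagreed, as one stood at 3126 signal units in the control and 9842 at 24 h while the other, the brightest, stood at 15872 and 17864. Only 17 genes were 2-fold or more higher at 24 h than at 12 h and 22 were lower, 0.316% of those measured, and no gene met the naming rule. Of 38 lists, 5 lay above and 5 below the random range.

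Cholesterol genes had a median of -0.29 between the treated arrays, and 17 of 19 were lower at 24 h, the exceptions being FDPS at 0.07 and TM7SF2 at 0.35. INSIG1 was at -0.83, MVD at -0.70 and HMGCS1 at -0.58. G2/M and mitosis genes had a median of -0.29, and 50 of 51 were lower, with CKS1B at 0.06 the exception. KIF11 was at -0.61 and ESPL1 at -0.59. G1/S genes had a median of -0.12 with 32 of 44 lower, E2F8 at -0.71. Homologous recombination genes had -0.19 with 23 of 25 lower. Metallothioneins had -0.43 with 7 of 7 lower, MT2A at -0.67. Signal of the 3' probe set of 18S ribosomal RNA was 1385 at 12 h and 8152 at 24 h, against 4903 in the control, and that of the 5' probe set was 9846, 14427 and 14296.

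Proteasome subunits had a median of 0.16 between the treated arrays and were higher at 24 h in 26 of 26 cases, PSMC4 at 0.36. NRF2 targets had 0.08 with 17 of 25 higher, a call not kept with transcript-specific probe sets. Immediate early genes had 0.13, with CCN1 at 0.29 and NR4A1 at least 1.90-fold higher. Ribosome biogenesis and MYC target genes had 0.11, with NOP16 at 0.55, after medians of -0.08 at 12 h and 0.02 at 24 h that lay within the random range, and MYC at -0.41 and -0.36 against the control. This call was not kept with the median over probe sets. Autophagy genes had 0.07, a call not kept with quantile normalization, cyclic loess, the floor at the 65th percentile or transcript-specific probe sets. The ATF4 list had 0.00 with 15 members higher and 15 lower, so its level was alike on both treated arrays.

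**Figure D2:**
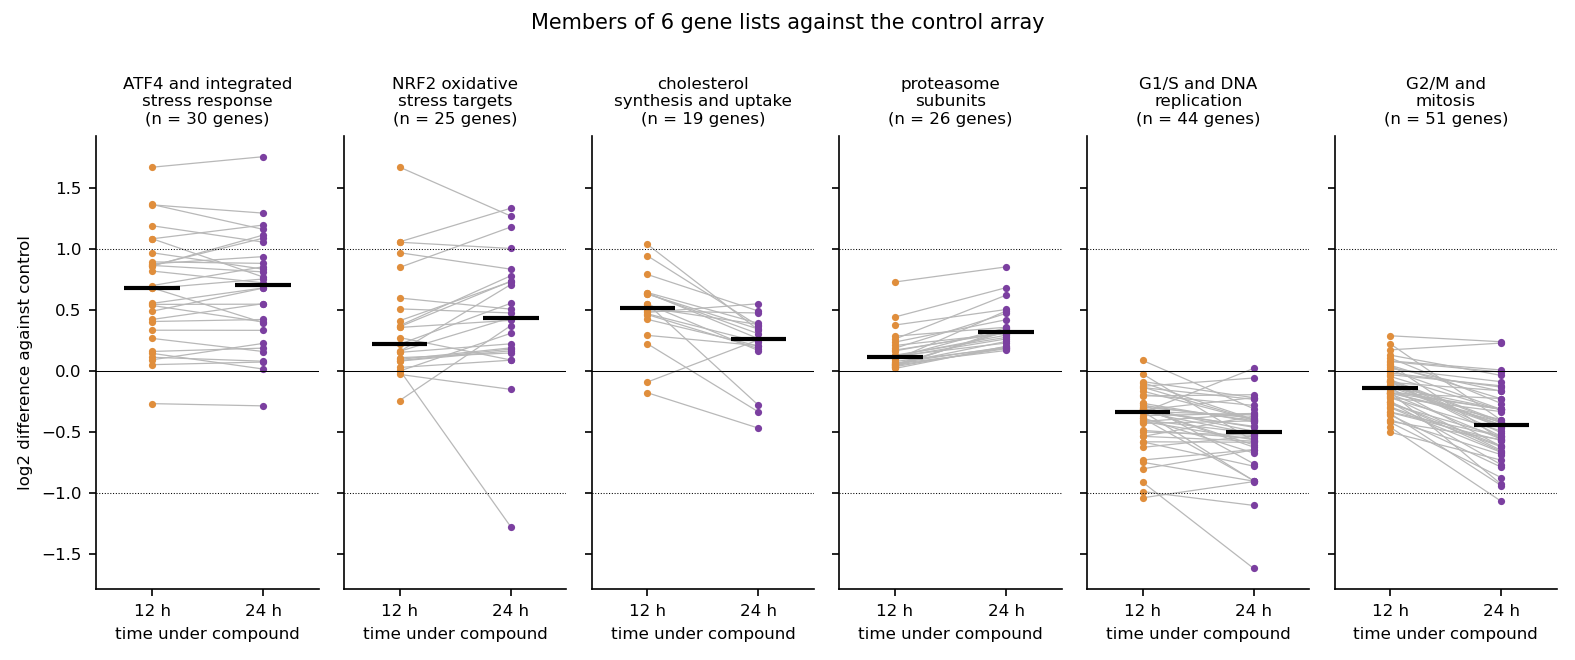
Each point is a measured member of 1 of 6 gene lists, as log2 difference from the control at 12 h (orange) and 24 h (purple), with a line joining the values of a gene, a black bar at the median and dotted lines at 2-fold. Sterol synthesis members sit lower at 24 h in 17 of 19 cases and mitotic members in 50 of 51, while proteasome members sit higher in 26 of 26.

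Of the genes 2-fold different at 12 h, 53 of 54 higher and 53 of 53 lower ones differed the same way at 24 h by any size. The shared control alone would give much of this, since simulated unchanged arrays had the same sign for 94.8% of the genes called at 12 h, against 99.1% observed. SLFN5, DDIT3, HMOX1 and GDF15 were among 29 genes 2-fold higher at both times, and ABCA1, TGFB2 and MOB3B among 22 that were lower at both. Independent sets of these sizes would share 0.306 and 0.331 genes, and the simulation shared 1.39 and 1.55 on average, from 26.3 genes called at 12 h in place of 107. Across 12341 genes, which are not independent replicates, Pearson's r between the differences at 12 h and 24 h was 0.73 and Spearman's rho 0.71, against 0.50 and 0.47 in the simulation. The covariance was 0.0784 against a simulated 0.0299, a difference of 0.0486, and 78.2% of genes had the same sign at both times against 66.8%. The simulation gave the control the noise of the treated arrays, and a noisier control would raise the simulated values. With a single control array it could not be split, and part of the overlap may come from it.

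**Figure D3:**
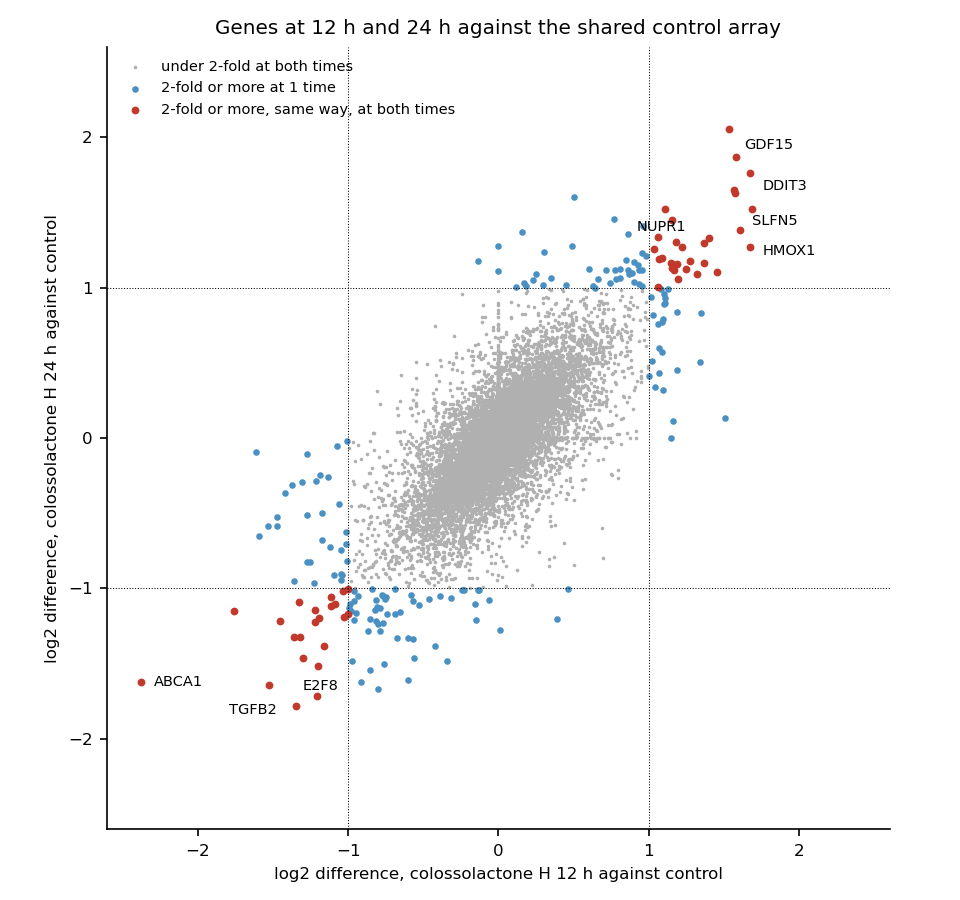
Each point is 1 of 12341 measured genes, with the log2 difference from the control at 12 h on the horizontal axis and at 24 h on the vertical axis, dotted lines at 2-fold, red for genes 2-fold different the same way at both times, blue for 1 time and grey for neither. DDIT3 and HMOX1 lie at upper right and ABCA1 at lower left.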

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

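The tests of growth state, of differences between single dishes and of longer time under the compound were chosen only after the results were seen, and the others in this part were set out beforehand. Some of those others are read here as open although their values passed the size set beforehand against the explanation. The exact interval given below was not part of the rule set beforehand.

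MAP kinase output genes had medians of opposite sign at the 2 times, -0.05 at 12 h and 0.16 at 24 h, with a median of 0.078 between the treated arrays that lay within the random range. TRIM16L, a relative of an NRF2-induced ligase gene, was at 0.01 at 12 h and -1.28 at 24 h, and its difference of -1.29 between the treated arrays was not tested. Spiked poly-A control transcripts, which no comparison used, had a geometric mean signal of 946.7 at 12 h against 724.5 in the control and 552.8 at 24 h. Among 4346 measured probe sets with no gene name, which the comparisons left out, 19 were 2-fold or more higher at 12 h and 24 lower, while at 24 h 84 were higher and 35 lower. Among 1143 measured probe sets of several genes, 5 were 2-fold higher and 4 lower at 12 h, and 10 were higher and 8 lower at 24 h.

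Replication and mitosis genes were lower at 24 h. Scaling that depends on signal level was argued against, since after cyclic loess the joined lists still had a median of -0.47 with 91 of 95 genes below 0. Like the deposited scale, cyclic loess aligns the bulk of the genes, so an error shared by all genes could not show. Spiked poly-A controls differed by -0.39 for 24 h against control, with 1 of 12 probe sets higher. Scaling on them was not run, so a shared scaling error stays open. RNA degraded from the 5' end stays open, and ACTB had a higher 3' over 5' ratio at 24 h. Such loss would spare the probe set nearest the 3' end. The least lowered probe set of the 47 list genes with several probe sets had a median of -0.36, and 42 of those genes were below 0. These values go against degradation only if the probe sets of a gene lie at different distances from the 3' end. Probe positions were not available to check this. Growth state of the cultures stays open beside an effect of the compound, since the labels give no collection time for the control, and the median of -0.20 between the treated arrays cannot separate the possibilities.

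Sterol synthesis genes were higher at 12 h than at 24 h. Under 3 other scalings of the treated arrays the list median closest to 0 was -0.28, so the list was lower relative to most genes. All 3 align the bulk of the genes, which the deposited scale already did, so an error shared by all genes could not show. Spiked poly-A controls differed by -0.78 for 24 h against 12 h, with 0 of 12 probe sets higher. Scaling on them was not run, so scaling between the treated arrays stays open. Error of single probe sets was argued against, because 19 other probe sets of 10 list genes had a median of -0.20 with 16 below 0. A response to the compound that wanes with time and a difference between single dishes cannot be told apart, since 17 of 19 genes being lower came from 1 dish at each time.

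More unnamed probe sets were higher than lower at 24 h relative to 12 h, 51 against 13. Among 1845 brighter ones 7 were higher and 2 lower, a ratio of 3.5 that goes against noise of low signals. With a share of 77.8% higher and an exact 95% interval of 40.0% to 97.2%, these counts are too few to exclude it. That interval treats probe sets of the same pair of arrays as independent, and it holds no spread between repeat arrays. Unspliced or genomic sequence stays open, as probe sets of named genes from the later design series were higher 68 times and lower 39 times among 10951, a ratio of 1.74 between the sizes set for and against it, while the earlier series, to which that explanation does not point, was higher 63 times and lower 24 times among 12357. Longer time under the compound also stays open, since the 84 probe sets higher than in the control at 24 h rest on 1 array.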

How the results depend on the processing

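No setting turned the direction of a called list or of a named gene 2-fold different from the control. Calls kept under each alternative that could give one were 10 of 14 lists and 19 of 28 named genes at 12 h, 13 of 17 lists and 21 of 30 genes at 24 h, and 7 of 10 lists for 24 h against 12 h. Lists within the random range gained a call under at least 1 alternative in 2 cases at 12 h (liver X receptor and FOXO targets), 1 at 24 h (heat shock) and 7 for 24 h against 12 h (heat shock, glucocorticoid receptor, NF-kB, MAP kinase, FOXO, lung lineage, and drug efflux genes). Under the other scalings the all-gene median lay between -0.04 and 0.03, and cyclic loess shared 103 of 107, 145 of 147 and 38 of 39 gene calls with the deposited scale. No paired analysis was possible because each group held 1 array. The floor and the threshold moved the gene counts most, and the floor also sets the number of genes kept. How far noise of dim genes accounts for the change in counts was not tested.

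Counts of genes 2-fold higher and lower moved as follows. A floor at the 25th percentile, with 17818 genes, gave 699 and 793 at 12 h, 733 and 873 at 24 h, and 695 and 751 for 24 h against 12 h. No floor with a pseudocount of 1, with 19775 genes, gave 1604 and 1753, 1630 and 1851, and 1684 and 1723. A floor at the 65th percentile, with 10029 genes, gave 26 and 18, 34 and 27, and 4 and 1. A 3-fold threshold, stricter by construction, left 4 and 4, 6 and 7, and 0 and 1. A local threshold of 3 robust SD gave 119 and 102 at 12 h, 96 and 79 at 24 h, and 136 and 120 for 24 h against 12 h, the reverse of the order at 2-fold, since it follows the spread at each signal level instead of a fixed size. The correlation of 0.73 between the differences at 12 h and 24 h was 0.56 with the floor at the 25th percentile, 0.78 at the 65th and 0.51 with none. It was 0.71 with the median over probe sets and 0.71 with transcript-specific probe sets, and the cause was not tested.

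Values of some genes below 2-fold depended on the probe set. Directions turned with transcript-specific probe sets for ABCC3, SDHC, DERL3 and NOP16, the last from -0.49 to 0.02 at 12 h, and as medians over probe sets for OGG1 at 12 h (0.19), CCND1 at 24 h (0.41), OAS3 at 24 h (0.03), SREBF2, ATF3 and COL1A1 at 12 h, HMMR at 24 h (-0.09) and NOP16 at 24 h (-0.06). Values close to 0 also changed sign for CCNB1 and SEL1L at 12 h and MDM2 at 24 h, as did HBB, near the floor, at 12 h. Other values shrank without turning, those of EBP (0.36 at 12 h and 0.10 at 24 h as medians over probe sets), XBP1 (0.06 at 12 h), DLC1 (-0.07 at 24 h), SREBF2 (-0.07 at 24 h), EGFR (-0.10 at 12 h), COL1A1 (-0.22 at 24 h) and TSC22D3 (0.33 at 24 h). BCL2L1 was larger, at -0.90 at 12 h, and THBS1 was larger with transcript-specific probe sets, at -1.32 at 24 h. The cause was not tested.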

Other observations

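The lists in this part, and the genes named from them, were chosen after their values or the data were seen, and each test used only members whose values had not been looked at before the prediction was set down.

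Aminoacyl-tRNA synthetases of the cytosol, which charge tRNAs for protein synthesis, were higher at both times. Of 17 measured members 16 were higher at 12 h and 17 at 24 h, with medians of 0.29 and 0.36. EPRS1 was at 0.51 and 0.53, CARS1 at 0.50 and 0.54 and YARS1 at 0.47 and 0.51. EPRS1 was at 1.51 at 24 h as the median over its probe sets, and YARS1 at 0.07 and 0.24 with transcript-specific probe sets. The mitochondrial synthetases went both ways, with 8 of 15 higher at 12 h and 6 at 24 h, and YARS2 at 1.02 and 0.51 beside MARS2 at -0.79 and 0.22.

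Genes that respond to transforming growth factor beta were lower, with medians of -0.26 at 12 h and -0.54 at 24 h over 17 members, of which 12 and 14 were lower. SMAD6, an inhibitory SMAD, was at -0.57 and -1.34, PMEPA1, a feedback inhibitor, at -0.62 and -0.87 and ID3 at -0.89 and -0.82. Other members did not follow, with ID1 at 0.41 and 0.67 and BAMBI at 0.47 and 0.23. TGFBI, bright at 12456 signal units in the control, was at -0.02 and 0.02, and TGIF1 was at 0.04 and -0.02. SMAD7 was at -0.16 and -0.28. The 12 h call was not kept with the median over probe sets. Targets of the growth regulators YAP and TEAD had medians of -0.36 and -0.35 over 18 members, of which 17 were lower at 12 h and 18 at 24 h, including DLC1 at -0.79 and -0.56, or -0.37 and -0.07 as medians over its probe sets, and PTPN14 at -0.45 and -0.50. CCN2 is in both lists.

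One hypothesis was that the cytosolic synthetases follow the ATF4 list, in which 4 of them were included. The 13 members not seen before had medians of 0.25 at 12 h and 0.28 at 24 h, above the random range at both times, which is consistent with it. The like hypothesis for mitochondrial synthetases was not borne out, since 14 unseen members had medians of -0.01 and -0.079, within the range.

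TGFB2, SMAD6, CCN2 and THBS1 were low on both treated arrays, and a lower response to transforming growth factor beta or lower YAP and TEAD output may accompany this. The 14 unseen genes of the first list had medians of -0.21 and -0.45, and the 14 of the other had -0.33 and -0.32, each below the random range at both times. Both tests came out as predicted, so they do not choose between these hypotheses. The 5 measured fibroblast and endothelial markers were also lower, with medians of -0.27 and -0.56, and fewer cells of another type were not tested as an explanation of the lower genes. The hypotheses stay open, and as both were drawn from these arrays they need repeat cultures with a control collected at each time.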
